A study of Mus musculus and Homo sapiens with 32 samples.

How the data were processed

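m6A-CT tagments RNA paired with cDNA at sites that an anti-m6A antibody binds in nuclei, and input libraries come from the same kind of nuclei tagmented without antibody. Per the labels, 16 m6A-CT and 16 input libraries form 16 groups of 2; whether the libraries of a group are independent cultures is not given. The antibody came from Synaptic Systems for E14, EPSC, MEF and HEK293T and from MilliporeSigma for the C57BL/6 genotype set, so the sets differ in antibody as well as in cells. According to the submitters' processing notes, reads were trimmed with Trim Galore, aligned with STAR 2.7.2 to mm9 or hg19 and called with MACS2, and each of the 6 resulting lists is filed under the first replicate; pooling of replicates is not stated. MeTPeak and exomePeak2, used for the genotype set, are named by the sample descriptions, without version or settings.

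In the 6 MACS2 lists the deposited score is 10 times -log10 q as a whole number. The deposited fold enrichment is the ratio at the summit against a background that is not stated. The deposited -log10 p and -log10 q are those of the caller, and -log10 q is at least 10 throughout. The deposited offset of the summit in bp is a position, one of the other columns that hold no measurement. In the MeTPeak lists the deposited score is a p-value, and other deposited columns give log10 of p and FDR and the number of exon blocks. The deposited fold is the caller's enrichment of m6A-CT over input. How it was computed is not stated, and it can lie far above the RPM ratio of much the same stretch. In the exomePeak2 table the deposited RPM values, 1 column per genotype and library kind, are whole multiples of 1 read to within 0.01 reads, which gives back the reads and the totals. The deposited log2 fold change compares the m6A-CT over input ratio of Mettl3 KO with that of wild-type, with an offset of the authors' model, and the deposited p-value comes with an FDR. The table holds regions past FDR 0.05 with few exceptions.

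Values per replicate were not analysed here, so edgeR on single libraries, named in the plan where such counts exist, was not run, and no test between replicates was made. Differences are given by the authors' p-value, and list values by their percentile among 10000 random lists. Those lists were matched on input level in 20 strata for the Mettl3 comparison and on listed exonic length for the peak lists. Shares of peaks carry Wilson 95% intervals and were compared with 1000 circular shifts of the second list along each chromosome. PCR reads without molecular identifiers are not independent molecules, so intervals, errors and bounds cover counting error alone. A column with no reads was taken at a floor of 3 reads over the group for a bound on the fold, given where the other columns had over 3 reads, which corresponds to 0.0763 RPM in wild-type m6A-CT, 0.0665 in wild-type input, 0.0799 in Mettl3 KO m6A-CT and 0.0588 in Mettl3 KO input. The counting error of a log2 fold change comes from the reads of its 4 columns. Depth per library, and any depth of the 6 MACS2 lists, is not given in the files.

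Peaks were called shared when they overlapped by at least 1 bp without regard to strand, and MeTPeak peaks when their exon blocks overlapped by at least 1 bp on the same strand. Mouse peaks were named from the exon blocks of the 3 genotype files, which pair mm9 positions with gene symbols and cover 11193 genes; synonyms were resolved with a RefSeq table of a later build that gave names alone. These blocks come from embryonic stem cells, so a gene active elsewhere may have no position. A gene with a position may be covered only in part, and its peaks outside the listed blocks stay unnamed. No mm9 or hg19 annotation was at hand, so peaks were not assigned to untranslated regions, coding sequence or introns, and human peaks were not named.

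The 14 gene lists were fixed before the data were examined: naive pluripotency, primed pluripotency and germ layers, trophectoderm and primitive endoderm, two-cell-stage genes, fibroblast and extracellular matrix, endothelial, blood and epithelial markers, m6A writers, erasers and readers, chromatin regulators, immediate early genes, interferon response, cytosolic ribosomal proteins, long noncoding RNAs, zinc finger transcription factors, and cell cycle. The rule for named genes was fixed then too. For the Mettl3 comparison it takes Mettl3, the 8 lowest and 8 highest log2 fold changes past FDR 0.05 with at least 50 reads, up to 4 members per list with the largest absolute change, and Nanog, Pou5f1, Sox2, Klf4 and Esrrb. For the peak lists it takes the 5 peaks of highest fold per list, up to 4 members per gene list with the highest fold in E14, EPSC or MEF, and Malat1, Neat1, Xist, Nanog, Pou5f1, Sox2, Klf4, Col1a1, Fn1 and Vim. Where 1 gene has several regions, the one with the most reads stands for it.

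The counting test was tested on simulated data, where 76.0% of 200 regions lowered 4-fold were recovered at FDR 0.05 among 30146 regions and 4.70% of unchanged regions had p under 0.05. The simulated reads held counting error alone, which the test assumes. How it fares with variation between libraries or with PCR copies is therefore not shown. Alternatives, with their effect in the closing section, were stricter -log10 q of 20 and 50, merging of peaks within 1000 bp, chromosomes left out, reciprocal overlap of 50%, summits within 200 bp, lists of equal length, a draw from the union of the mouse lists, whole spans, no strand, MeTPeak FDR of 0.005 or fold of 2, exomePeak2 FDR of 0.01 and 0.1, unadjusted p, at least 50 reads, RPM ratios with pseudocounts of 1 and 0.1, 1 region per gene, and regions in wild-type peaks. Scalings without the authors' offset and without Lars2 and Rn45s were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used.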

Results

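Bulk m6A-CT, an antibody-directed tagmentation of RNA paired with cDNA inside permeable nuclei, was used to place N6-methyladenosine (m6A), a methyl mark on RNA, along transcripts. The series holds 32 libraries in 16 groups of 2, and every m6A-CT group has an input group made by tagmentation without antibody. The cells were mouse E14 embryonic stem cells at 100K, 25K and 5K nuclei, expanded potential stem cells (EPSC, derived here from E14), CF1 mouse embryonic fibroblasts (MEF) and the human line HEK293T, each of the last 3 at 100K nuclei. A further 8 libraries came from C57BL/6 mouse embryonic stem cells that were wild-type or labelled as knockout (KO) of Mettl3, the catalytic subunit of the m6A writer complex. The deposited files give 6 peak lists, 2 peak lists by genotype and 1 table that compares the genotypes. None of them holds a value per replicate, so no replicate error can be given anywhere below, and all intervals cover counting error alone. Depth can be read from the genotype table, where the pooled totals were 39310394 reads for wild-type m6A-CT, 45090626 for wild-type input, 37532658 for Mettl3 KO m6A-CT and 51031598 for Mettl3 KO input; for the 6 other lists it is unknown.

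The E14 lists ask how far the peak set holds when fewer nuclei are used. The RNA of the methylcytosine oxidase gene Tet1 carried 10, 11 and 5 peaks at 100K, 25K and 5K nuclei. Rif1, a replication timing factor, went from 21 peaks at 100K to 6 at 25K and 4 at 5K, and the noncoding RNA Tug1 had 4, 4 and 1. Members of the naive pluripotency list with a peak numbered 19, 14 and 16 of the 31 that could be named, and chromatin regulators 31, 23 and 31 of 40. Among cytosolic ribosomal proteins, 9, 1 and 3 of 53 had a peak.

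In all, the authors listed 8052 peaks at 100K, 3923 at 25K and 4644 at 5K, with median lengths of 216, 181 and 179 bp. Of the 25K peaks, 75.6% (Wilson 95% interval 74.3 to 76.9) overlapped a 100K peak, against 51.0% (49.6 to 52.5) of the 5K peaks. In the other direction 34.2% of the 100K peaks were found at 25K and 28.4% at 5K. Random circular shifts of the 100K list gave mean shares of 0.260% for 25K peaks and 0.248% for 5K peaks, and random choices from the union of the mouse lists gave 16.8% and 16.7%. Merged into 11011 regions, the lists shared 1720, while 4737 were in the 100K list alone and 2018 in the 5K list alone. Peaks of exactly 100 bp made up 9.92% of the 100K list, 21.3% of the 25K list and 22.1% of the 5K list. With 1 list per amount, no test between amounts was possible.

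Most of the 5 highest peaks by fold enrichment in each mouse list lay outside the exons that the files name. The authors' fold values serve here only to rank peaks within a list. At mm9 chr6:145881266-145881598 the E14 list at 100K had its highest value, 688-fold, and a peak there also led the lists at 25K (953-fold), at 5K (659-fold) and in MEF (81.2-fold). The next places in E14 at 100K went to 100-bp peaks at chr16:57441901-57442000 (626-fold), chr9:4328961-4329060 (389-fold), chr16:57635513-57635612 (342-fold) and chr19:8402806-8402905 (293-fold). Among the top 5 of each mouse list, Celsr1, a planar cell polarity cadherin, was named in EPSC at chr15:85729506-85731165 (239-fold), and Fat1, a giant cadherin, in MEF at chr8:46095067-46096050 (63.9-fold). The MEF peaks at chr3:38876107-38876524 (72.7-fold) and chr10:119896882-119899936 (49.9-fold) met no peak of another mouse list. Every other top peak of the mouse lists met a peak in each of the 5 lists. The 100-bp peak at chr16:57441901-57442000 had the same start and end in E14 at 100K, in E14 at 25K and in EPSC. Whether such recurrent peaks mark m6A was not tested. HEK293T, an embryonic kidney line, had 32975 peaks with a median length of 267 bp, led on hg19 by chr16:72979615-72979714 (90.9-fold) and chr8:56754968-56755392 (90.5-fold); gene names were not assigned to them, because no file pairs human genes with positions.

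EPSC, E14 and MEF were compared at 100K nuclei to show which transcripts carried peaks in each cell type. Collagen and matrix genes stood apart: Col6a3 (22-fold), Col5a1 (17.6-fold, 15 peaks) and Fbn1, the fibrillin gene (11.0-fold), had peaks in MEF and none in E14 or EPSC. Rian, an imprinted noncoding RNA, did the reverse, with 9 peaks in E14 (35.9-fold), 7 in EPSC (17.8-fold) and none in MEF. Cdh1, the epithelial cadherin, had 6 peaks in E14, 13 in EPSC and none in MEF. Fn1, fibronectin, had many in all 3, at 33, 39 and 43. Zfp608, a zinc finger gene, carried 1 strong peak in E14 (78.1-fold) and EPSC (35-fold) and none in MEF.

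Across the naive pluripotency list, 19 of 31 nameable members had a peak in E14, 20 in EPSC and 10 in MEF, at percentiles 100, 99.9 and 0.40 of random gene lists matched on listed exonic length. That length covers exons listed in C57BL/6 embryonic stem cells, and expression in these cell types was not matched. A gene without a peak may thus be unmethylated or little expressed, which was not told apart. Rif1 (21.2-fold in E14, 30.1 in EPSC, 14.3 in MEF), Tet1 (14.0, 19.5 and 6.90), Tet2 (7.46, 11.4 and 10.8) and the LIF receptor gene Lifr (8.26, 6.73 and 11.3) had peaks in all 3 cell types. So did Klf4 (3.68-fold, 3.68-fold and 9.56-fold), while Sox2 had them in E14 (1.57-fold) and EPSC (2.64-fold), and Nanog in E14 (3.00-fold). Pou5f1, the gene of the pluripotency factor Oct4, had no peak over its listed exon stretches in any of the 3, nor did Xist or Vim, and Col1a1 has no position in the files. Those stretches can be a small part of a gene, with 2 regions for Pou5f1 and 1 for Vim. A peak elsewhere in such a gene would be missed. The fibroblast and extracellular matrix list had 14 of 19 nameable members with a peak in MEF, 11 of them in MEF alone, against 1 in E14 and 3 in EPSC (percentiles 100, 8.66 and 25.1). With as many peaks from each list as E14 has, the counts for E14, EPSC and MEF were 19, 19 and 4 for naive pluripotency, 1, 2 and 8 for fibroblast and 1, 4 and 8 for immediate early genes. Zeb1, a driver of mesenchymal identity, was at 10.7-fold in MEF and 7.96-fold in EPSC. Immediate early genes, which stress and serum switch on, had a peak in 14 of 17 members in MEF (Jun at 6.80-fold, Klf6 at 5.96-fold, Egr1 at 5.37-fold, Nr4a1 at 3.33-fold), in 6 in EPSC and in 1 in E14, Klf6 at 9.76-fold. Their percentiles were 100 in MEF, 80.7 in EPSC and 12.9 in E14.

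Long noncoding RNAs had a peak in 12 of 14 members in E14, 13 in EPSC and 4 in MEF. Tug1 (27.7, 16.3 and 15.0-fold in E14, EPSC and MEF), Malat1 (5.89, 6.41 and 11.4-fold) and Neat1 (4.28, 4.98 and 14.0-fold) were marked in all 3 cell types, and Snhg5 in E14 (10.8-fold) and EPSC (20.8-fold). Cytosolic ribosomal protein genes, of which 53 were nameable, had a peak in 9 members in E14, 11 in EPSC and 1 in MEF, with Rpl3 at 12.6-fold in E14 and 8.19-fold in EPSC, and Rps12 at 6.15 and 11.5-fold. Zinc finger genes (19, 20 and 20 of 23, with Zbtb10 at 58.0, 14.4 and 11.7-fold) and chromatin regulators (31, 34 and 36 of 40, with Kmt2c at 10.1, 10.1 and 20.0-fold) were marked in most members of each cell type. Of the m6A writers, erasers and readers, 11, 18 and 16 of 21 had a peak, among them the writer subunit genes Virma (5.93, 6.73 and 14.8-fold) and Zc3h13 (11.2, 7.57 and 9.53-fold). Cell cycle genes had 7, 8 and 10 of 27, with Top2a at 11.3, 7.59 and 5.64-fold and Mki67 at 6.6, 10.1 and 10.5-fold. With lists of equal length the order of E14 and MEF turned for the m6A machinery (11, 12 and 6), cell cycle genes (7, 7 and 5), chromatin regulators (31, 31 and 30) and zinc finger genes (19, 19 and 14), while long noncoding RNAs (12, 10 and 3) and ribosomal protein genes (9, 9 and 0) still had fewest in MEF. Smaller counts came from primed and germ layer genes (1, 3 and 0 of 12, with Nes at 6.11-fold in E14 and 7.32-fold in EPSC), trophectoderm and primitive endoderm genes (2, 3 and 5 of 13, with Lama1 at 9.29 and 11.1-fold in E14 and EPSC) and interferon genes (1, 2 and 3 of 12, with Adar at 6, 7 and 9.31-fold), and at equal length the trophectoderm group had 2, 3 and 2 and the interferon group 1, 0 and 1. Endothelial, blood and epithelial markers, held as signs of other cells, had 2, 4 and 0 of 13, with Grhl2 at 8.18-fold in EPSC, and of the two-cell-stage genes only 1 of 19 could be named, without a peak.

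**Figure D1:**
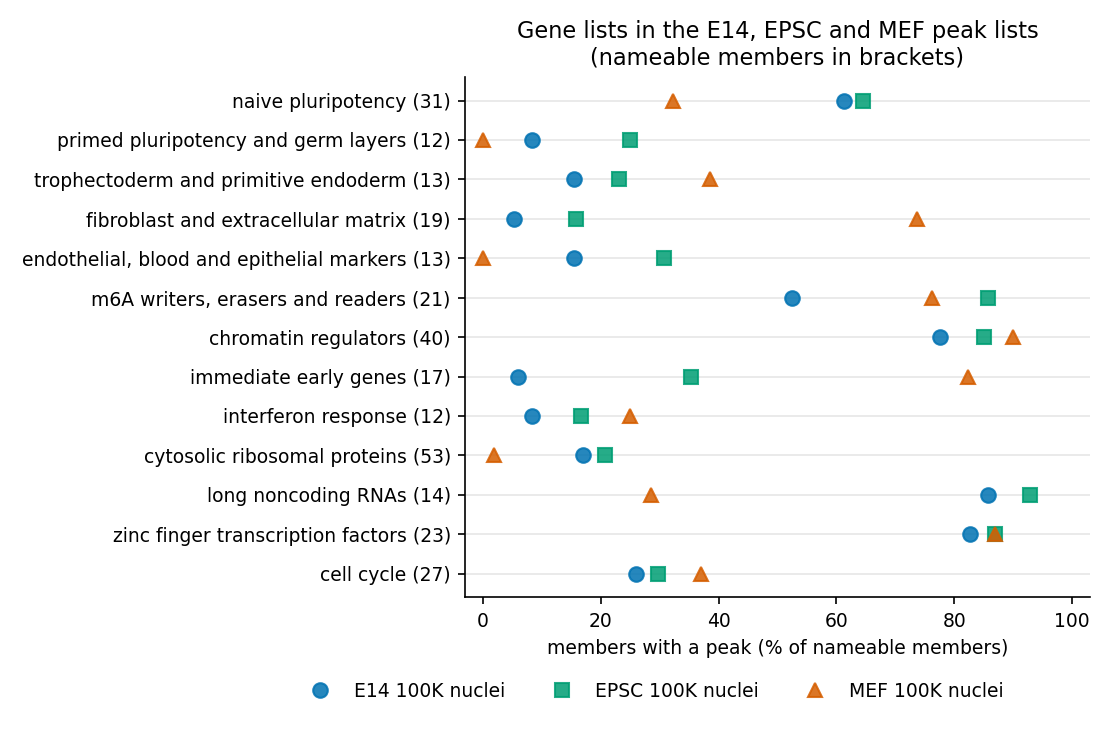
Share of each gene list's nameable members (number in brackets) with at least 1 m6A-CT peak, on the horizontal axis in percent, for E14 (circles), EPSC (squares) and MEF (triangles) at 100K nuclei, 1 list per cell type. MEF is to the right for the fibroblast (14 of 19) and immediate early genes (14 of 17) and to the left for the naive pluripotency genes (10 of 31) and long noncoding RNAs (4 of 14), as it is with lists of equal length (8, 8, 4 and 3 members).

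E14 had 8052 peaks, EPSC 12183 and MEF 38205, so the lists differ in length as well as in content. Of the E14 peaks, 67.5% (66.5 to 68.6) were found in EPSC and 55.9% (54.8 to 57) in MEF, and of the EPSC peaks 62.0% (61.1 to 62.9) were found in MEF. Merged, the 3 lists gave 44148 regions, of which 30194 (68.4%) were in MEF alone, 2615 in EPSC alone, 1558 in E14 alone and 3236 (7.33%) in all 3. With as many peaks from each list as E14 has, the share of E14 peaks found in MEF was 26.7% and that of EPSC peaks 31.8%. Names rest on exons listed in embryonic stem cells, which leaves 21 of the 40 fibroblast genes without a position, and 65.9% of E14 peaks, 77.0% of EPSC peaks and 73.5% of MEF peaks with a gene.

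**Figure D2:**
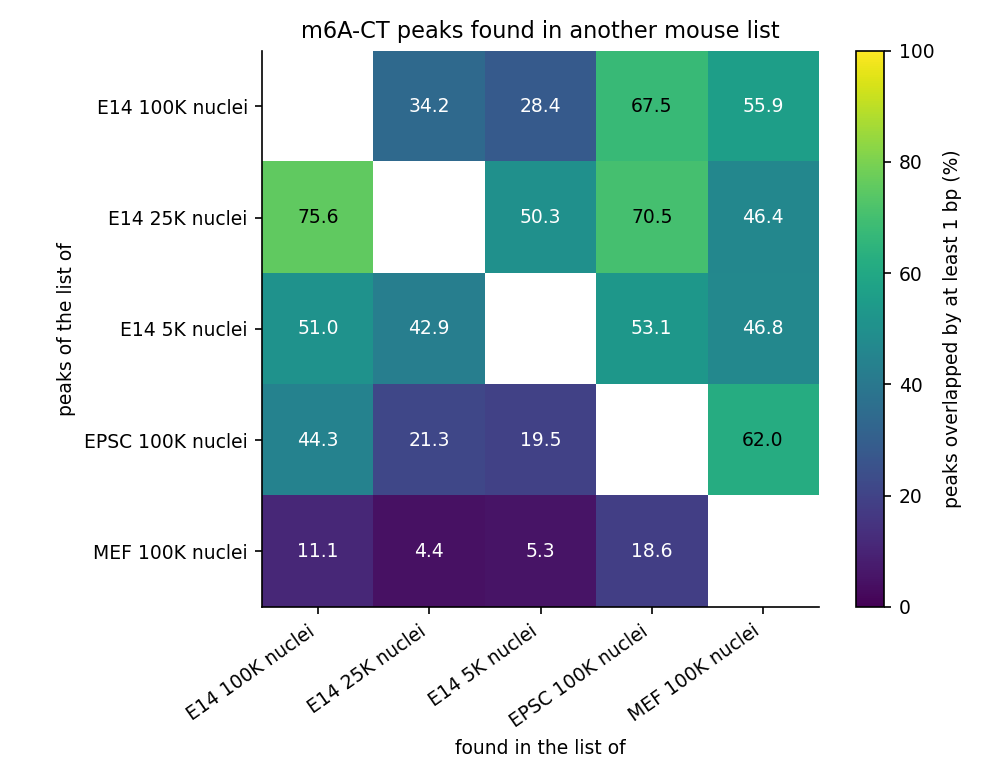
Percent of the m6A-CT peaks of the list named on the vertical axis that overlap a peak of the list on the horizontal axis by at least 1 bp, for the 5 mouse lists. The shares run from 4.38% for MEF peaks in the E14 list at 25K to 75.6% for E14 peaks at 25K in the 100K list.

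The genotype peak lists ask how m6A-CT enrichment over input differs between libraries labelled wild-type and Mettl3 KO. Sox2, a core pluripotency gene, had a highest fold enrichment of 36.8 in wild-type and 6.50 in Mettl3 KO in the authors' MeTPeak lists. Klf4, another pluripotency factor gene, was at 39.1 and 16.5, the growth factor gene Fgf4 at 37.2 and 8, the LIF co-receptor gene Il6st at 37.5 and 7.43, and Tet2 at 57.5 and 14.3. Zfp568, a KRAB zinc finger gene, was at 38.0 and 5.92, Tug1 at 57.5 and 5.50, and the chromatin remodelling gene Arid1a at 39.5 and 9.19. Nanog, at 8.43 and 8.57, was not lower in Mettl3 KO.

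By group, the highest fold was lower in Mettl3 KO for all 19 zinc finger genes with a peak in both genotypes, 29 of 36 chromatin regulators and 18 of 23 naive pluripotency genes. It was lower for 11 of 17 m6A writers, erasers and readers, where Rbm15 went from 21.7 to 5.40, and for 6 of 14 cell cycle genes, where Bub1 had 4.33 in wild-type and 9 in Mettl3 KO. Ribosomal protein genes ran the other way, with a peak in 23 members in wild-type and in 42 in Mettl3 KO, and a lower fold in 5 of the 23 found in both. Long noncoding RNAs (7 of 8), immediate early genes (6 of 7), fibroblast genes (4 of 5), trophectoderm genes (4 of 4), primed genes (2 of 3), endothelial, blood and epithelial markers (3 of 3) and interferon genes (2 of 2) had few members in both lists, and no two-cell-stage gene had a peak in either. The highest folds of all were those of Nufip2 (104), Zbed6 (86.5), Celsr1 (82.2), Mga (81.7) and Klf9 (77.0) in wild-type, and of the ribosomal RNA precursor Rn45s (62.1), Tet1 (38.7), Atp2a2 (31.5), Zfp985 (31.0) and Zfp980 (30.8) in Mettl3 KO. Over a region that covers the Rn45s peak, m6A-CT over input by RPM was only 0.32 in wild-type and 0.49 in Mettl3 KO. That scale thus shows no enrichment of Rn45s.

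The authors listed 20055 wild-type peaks in 5838 genes and 20482 Mettl3 KO peaks in 4635 genes; 3953 genes had peaks in both, 1885 in wild-type alone and 682 in Mettl3 KO alone. Median fold enrichment was 3.71 in wild-type and 3.25 in Mettl3 KO, and 2129 wild-type peaks against 540 in Mettl3 KO reached 10-fold. The genotypes were not alike in depth over most genes. By the genotype table, reads outside Lars2 and Rn45s made up 63.5% of wild-type and 45.5% of Mettl3 KO m6A-CT reads, on totals of 39310394 and 37532658. Peaks were not called at equal depth, so its effect on the numbers of peaks and genes and on the folds was not tested. In genes with a peak in both, the highest fold was lower in Mettl3 KO in 3032 of 3953 (76.7%, 75.4 to 78), at medians of 8.20 and 5.45. A peak in the other genotype overlapped 52.9% (52.2 to 53.6) of wild-type peaks and 75.7% (75.1 to 76.3) of Mettl3 KO peaks on the same strand. Wild-type peaks were longer, with a median of 299 exonic bp against 250 and 14.5 Mb in all against 10.8. With overlap of at least 50% of both peaks required, these shares were 22.1% and 21.7%.

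**Figure D3:**
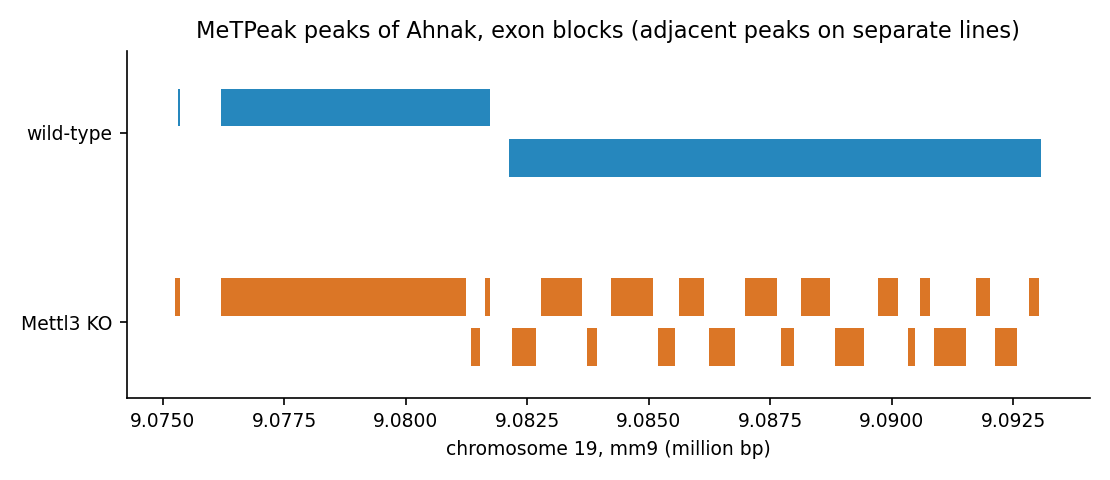
Exon blocks of the authors' MeTPeak peaks in Ahnak on mm9 chromosome 19 (horizontal axis, Mb), wild-type above and Mettl3 KO below, with neighbouring peaks drawn on separate lines. The 2 wild-type peaks had folds of 40.5 and 51.8 and the 21 Mettl3 KO peaks had folds from 2.67 to 10.2. Over its listed region with the most reads, Ahnak input RNA was 6.99-fold lower in Mettl3 KO, and this gene was chosen after its values were seen.

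The authors' exomePeak2 table compares the same libraries region by region, as the change in Mettl3 KO of m6A-CT reads over input reads. In the authors' deposited table Sox2 fell by 1.55 (log2, counting SE 0.04), Klf4 by 1.15 (0.06), Tet2 by 1.90 (0.07), Fgf4 by 2.16 (0.06), Il6st by 2.22 (0.09) and Tbx3 by 1.79 (0.07). On the RPM scale, without the offset of the authors' model, these were -1.05, -0.61, -1.42, -1.63, -1.70 and -1.29, and without the reads of Lars2 and Rn45s -0.89, -0.44, -1.25, -1.47, -1.54 and -1.12. For Sox2, 296 RPM of m6A-CT over 106 RPM of input in wild-type became 112 over 82.7 in Mettl3 KO. Those are ratios of 2.80 and 1.35, far below its MeTPeak folds of 36.8 and 6.50, so these measures are not on a common scale. Esrrb (-1.01; -0.50 and -0.34 on these scales) and Nanog (-0.80; -0.28 and -0.11) fell less in the authors' deposited table, and Pou5f1 was higher (0.23, FDR 0.012; 0.70 and 0.87). The RPM ratio of the Pou5f1 region was 0.63 in wild-type and 1.03 in Mettl3 KO, so it was not enriched in wild-type on this scale. Arid1a (-2.34), Kmt2a (-2.12), Kmt2d (-2.09) and Ring1 (-2.96), all genes of chromatin proteins, fell in the authors' deposited table, as did Rbm15 (-2.22) and Rbm15b (-2.22), which encode adaptors of the writer complex; these 6 were from -2.47 to -1.61 on the RPM scale and from -2.31 to -1.44 without both regions.

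Mettl3 itself has 1 listed region, at mm9 chr14:52919391-52919765, which the authors' deposited table gives as 0.80 higher (counting SE 0.30, FDR 0.0376, 462 reads; 1.30 on the RPM scale and 1.46 without Lars2 and Rn45s); which part of the gene was removed is not given. Per the table's RPM columns, input reads of this region were not lower in Mettl3 KO, at 1.71 RPM in wild-type and 2.47 RPM in Mettl3 KO (log2 0.53, 0.12 to 0.94). In the MeTPeak lists Mettl3 had 1 peak in Mettl3 KO, with a fold of 2.27, and none in wild-type. Mettl14, the partner of Mettl3 in the writer, was higher by 2.13 (125 reads) in the authors' deposited table, and the mitotic kinase gene Cdk1 by 1.47 (353 reads). By RPM, m6A-CT over input in wild-type and Mettl3 KO was 0.28 and 1.13 for Cdk1, 0.88 and 2.16 for Mettl3, and 1.72 and 8.84 for Mettl14. The Cdk1 and Mettl3 regions were thus not enriched in wild-type on this scale. Whether these rises reflect m6A was not tested. In the authors' deposited table Tug1 fell by 2.76, the E2F factor gene E2f3 by 1.77, the p53 ligase gene Mdm2 by 1.48, and the zinc finger genes Zfp568 by 1.90, Zkscan3 by 1.84 and Zfp281 by 1.79. Jun (-1.68), Egr1 (-2.49) and the phosphatase gene Dusp6 (-2.98) fell, while Atf3 was higher (2.21, 66 reads), by the authors' deposited table. The RPM ratio of the Atf3 region was 0.78 in wild-type and 5.21 in Mettl3 KO. Ascl2 (-3.45), Snhg12 (-2.19), Gas5 (-1.76) and Zfhx4 (-2.35) were lower on 55 to 262 reads in the authors' deposited table. Ahnak (-1.32; -0.62 without Lars2 and Rn45s), Malat1 (-0.78; -0.12 likewise) and Neat1 (-0.72; -0.02), chosen after their values were seen, were lower too in the authors' deposited table. The other genes of this paragraph kept their sign on both scales, but not their size. Without Lars2 and Rn45s the falls shrank, to -1.07 for E2f3, -0.86 for Mdm2, -1.21 for Zfp568 and -1.05 for Jun. The rises grew, to 2.53 for Mettl14, 2.16 for Cdk1 and 2.90 for Atf3.

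The lowest values among regions with at least 50 reads were those of Abca1, Ankrd24, Scarf1, Kcnh2, Grin2d, Fan1, P3h3 and Dennd3, and the highest those of Atg3, Flot1, Prom1, Cmtr1, Herc3, Dock4, Rnf144a and Patj. They rest on 50 to 113 and 51 to 71 reads, and 7 of each 8 have a column at 0, so most of the folds are bounds. Where the other columns had over 3 reads, these were at least 12.9 to 22.3-fold lower (5 genes) and at least 9.40 to 33.2-fold higher (7 genes) on the RPM scale. A further 27 list members that the naming rule takes have 8 to 47 reads each, 21 of them lower and 6 higher, among them Gata6, Dab2, Col6a3, Rian, Ythdc2, Rpl3 and Meis1.

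**Figure D4:**
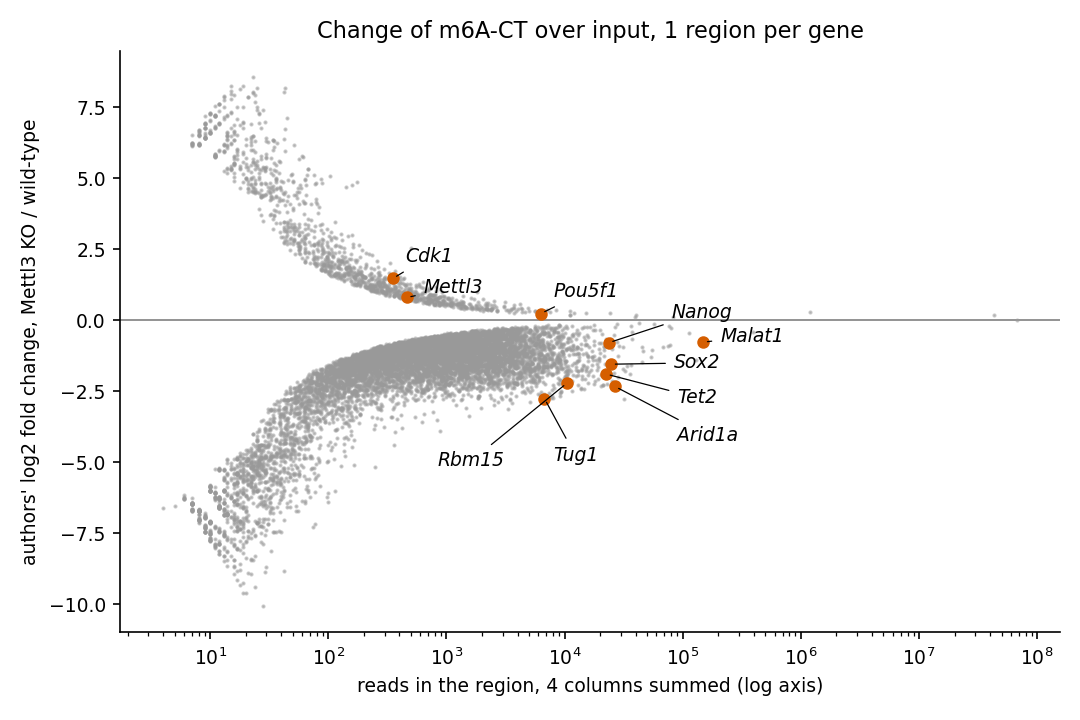
Authors' log2 fold change of m6A-CT over input in Mettl3 KO against wild-type (vertical axis) by the reads of the region in the 4 pooled columns (horizontal axis, log scale), 1 region past FDR 0.05 per gene, 10220 genes, with 10 genes marked. Most points lie below 0, and both branches bend away from 0 where reads are few.

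In the authors' deposited table, 33391 regions passed FDR 0.05, of which 29724 (89.0%) were lower in Mettl3 KO and 3667 higher, with a median log2 fold change of -1.34 (-1.33 with 3 reads in columns at 0). By gene, 8302 had lower regions alone, 1035 higher alone and 883 both. The authors' log2 values have a median offset of -0.50 from the same ratio of RPM values, and 90.6% of regions lie within 0.1 of it. The regions listed under Lars2 and Rn45s hold the most reads; Rn45s is ribosomal RNA, and whether the reads under Lars2 are too was not checked, for want of a genome. They take 36.5% of wild-type m6A-CT, 76.4% of wild-type input, 54.5% of Mettl3 KO m6A-CT and 81.0% of Mettl3 KO input reads. Leaving these reads out raises every RPM-scale value by 0.17. Over the 31111 regions with reads in every column, the medians were -1.31 on the authors' scale, -0.82 on the RPM scale and -0.65 without both regions, and 90.1%, 87.8% and 83.4% were below 0. The authors' p matches a counting test on pooled reads in 98.5% of 31087 regions, so it holds no replicate error, and the table lists few of about 155741 tested regions that did not pass.

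Lists of genes were set against random genes of like input level, 1 region per gene. Ribosomal protein genes lay above such genes, with a median of -0.65 over 31 listed members (percentile 99.9), but over the 28 with reads in every column it was -0.53 on the authors' scale, 0.007 on the RPM scale and 0.17 without Lars2 and Rn45s, so that their direction turns with the scaling. Their reads may also be shared with pseudogenes. Cell cycle genes had a median of -0.60 over 24 members (percentile 99.9), and over 23 it was -0.62, -0.08 on the RPM scale and 0.09 without both regions, with 18, 12 and 7 members lower. Zinc finger genes lay below random genes (median -1.43, percentile 2.28), and 22 of 23 were lower on the authors' and the RPM scale and 21 without both regions; with means over all regions of a gene their percentile was 13.4.

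The other lists lay within the central 95% of random lists. Listed were 29 of 36 naive pluripotency genes, 18 of 40 fibroblast genes, 12 of 26 interferon genes and 9 of 26 long noncoding RNAs. Naive pluripotency genes had a median of -1.08 (percentile 37.2), lower in 26 of 29 members on the authors' scale and in 24 without Lars2 and Rn45s. Without these regions the median was -0.44 for naive pluripotency genes, -0.51 for chromatin regulators and -0.52 for immediate early genes. Over members with reads in every column it was -0.43 for long noncoding RNAs, -0.84 for fibroblast genes and -1.32 for trophectoderm and primitive endoderm genes. Chromatin regulators were at -1.18 (percentile 20.5; 38 of 39 lower, 33 without both regions), immediate early genes at -1.20 (percentile 49.2; 16 of 17, then 15) and the m6A writers, erasers and readers at -0.79 (percentile 94.9; 14 of 20, then 11, where the median was -0.10). Fibroblast genes were at -2.20 (percentile 3.79; -1.66 with 3 reads in columns at 0), trophectoderm and primitive endoderm genes at -2.12 (percentile 5.45; 12 of 12 lower on every scale), interferon genes at -1.65 (percentile 47.6; -1.36 with 3 reads in columns at 0), endothelial, blood and epithelial markers at -1.63 (percentile 56.7; -1.31 likewise), long noncoding RNAs at -1.12 (percentile 83.0) and primed genes at -1.07 (percentile 86.0). The two-cell-stage list had 1 listed member, Arg2, with 8 reads.

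**Figure D5:**
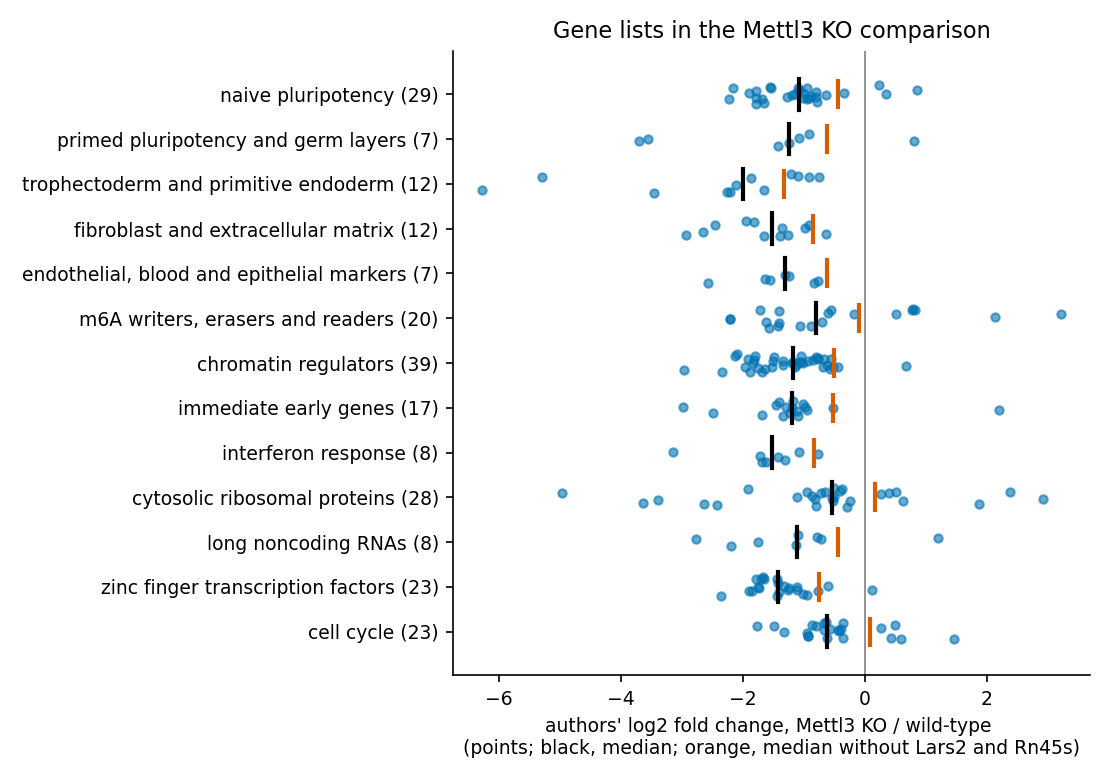
Authors' log2 fold change in Mettl3 KO against wild-type (horizontal axis) of each list's members with reads in every column (points, number in brackets), with their median (black) and the median without the reads of Lars2 and Rn45s (orange). Medians without these reads are above 0 for ribosomal protein genes (0.17) and cell cycle genes (0.09), and below 0 for the other lists.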

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

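Chosen after the results were seen were the tests on the RPM scale, without Lars2 and Rn45s and on broken peaks; those on overlap with E14 peaks and on 100-bp peaks were set beforehand, but the bound for 100-bp peaks was rewritten after its value was seen, with the same outcome.

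The input libraries of the genotype set serve above, but for Mettl3 and Ahnak, only as the background of m6A-CT, and they hold differences of their own. Among 2096 genes with at least 500 input reads, 11 were at least 4-fold lower in Mettl3 KO input and 9 at least 4-fold higher (9 and 16 without Lars2 and Rn45s). The noncoding RNA Lncenc1, expressed in naive embryonic stem cells, went from 57 to 3.25 RPM, 17.5-fold lower. Plagl1, an imprinted zinc finger gene, was 16.4-fold lower, Eppk1 (epiplakin) 13.7-fold, the imprinted gene Peg10 7.61-fold and Ahnak 6.99-fold lower. Kif26a, a kinesin family gene, was 7.84-fold higher, and the ribosomal protein gene Rpl29 went from 4 to 1082 reads. These 7 were chosen after their values were seen, with no replicate error to set them against. Reads of Rpl29 may also be shared with pseudogenes.

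Of the regions that passed in the genotype table, 89.0% were lower in Mettl3 KO. At the same bound on p, 81.6% were lower on the RPM scale and 75.8% without Lars2 and Rn45s, but the table was selected under the authors' offset and lacks regions that would be higher on these scales, so their part in the pattern cannot be told apart from the genotype. Regions lower in Mettl3 KO overlapped an E14 peak, from other cells and another antibody, 2.00 times as often as higher ones of like input reads and length (interval 1.66 to 2.48; 5.30% against 2.65%). Loss of m6A at methylated sites would give this, but so would the way regions were sorted. Regions were not matched on wild-type m6A-CT reads, and a high wild-type ratio by itself favours a call of lower. The overlap therefore cannot decide between them. The interval also treats regions as independent, although 1 gene can hold many. A weaker pulldown in the Mettl3 KO libraries would also lower enriched regions more, and stays open with 1 pooled value per genotype.

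E14 gave fewer peaks at 25K and 5K than at 100K nuclei, and fewer of the 5K peaks were in the 100K list. Stacks of reads that give 100-bp peaks could lower that share. Peaks of 100 bp in the 5K list were found in the 100K list 47.2% of the time and longer ones 52.1%, a difference of -4.95 percentage points (-8.39 to -1.49), where the 25K list had -12.7. The interval reaches past the 5 points first set as the limit for no effect, but stays short of the 20 set for stacks as the cause. Longer 5K peaks thus stayed far below the 75.6% of all 25K peaks, so the 100-bp peaks alone do not account for the lower share. Stacks that reach past 100 bp count as longer peaks here, so stacks as such are not excluded. Depth, which the files do not give, stays open, and the cells are alike by design, so no biological explanation was tested.

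Mettl3 KO had about as many MeTPeak peaks as wild-type, over fewer genes. Wild-type peaks that met at least 2 Mettl3 KO peaks numbered 3875, against 2358 in the reverse, a ratio of 1.64. Long peaks broken into pieces would give this ratio, but so would the greater length of wild-type peaks (median 299 against 250 bp) whatever its origin, so broken peaks cannot be told apart from separate shorter ones. Whether m6A that remains in Mettl3 KO adds peaks was not tested. Nor was the effect of depth, as Mettl3 KO had fewer m6A-CT reads outside Lars2 and Rn45s than wild-type.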

How the results depend on the processing

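The scalings on RPM values without the offset and without Lars2 and Rn45s were tests chosen after the results were seen, as was the interval by which a median counts as moved. In the exomePeak2 table more regions were lower than higher under every setting below. The order of lists turned in places, and the cause was not tested for any value that follows. At -log10 q of at least 20, E14 at 100K, 25K and 5K, EPSC, MEF and HEK293T kept 3513, 1877, 2002, 5749, 23961 and 16560 peaks, and at 50 they kept 1249, 922, 869, 1666, 11077 and 5190, so that 25K then had more peaks than 5K. Merging peaks and leaving out chromosomes held all 6 counts within 1.5 times.

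The shares of 25K peaks in 100K, 5K in 100K, E14 in EPSC, E14 in MEF and EPSC in MEF were 54.8, 36.4, 55.1, 35.4 and 43.4% with 50% of both peaks overlapped, 64.4, 45.4, 59.1, 44.1 and 51.1% with summits within 200 bp, 78.8, 59.9, 71.5, 48.8 and 58.1% at -log10 q of 20, and 60.5, 42.7, 56.7, 26.7 and 31.8% with lists of equal length. A random choice from the union of the mouse lists gave 16.8% for 25K and 16.7% for 5K peaks in the 100K list, far above the shares by shifts. Wild-type and Mettl3 KO MeTPeak shares were 22.1 and 21.7% at 50% of both peaks, where their order turned, and 52.2 and 76.7% at a fold of at least 2, and stayed within their intervals with whole spans, no strand and FDR of at most 0.005. At that fold wild-type had more peaks, 18468 against 18175, where all peaks gave 20055 and 20482.

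In the exomePeak2 table, FDR under 0.01 left 1545 higher regions and a median of -1.41, at least 50 reads gave -1.30, and pseudocounts of 1 and 0.1 on RPM gave -0.52 and -0.82. With 1 region per gene, 8941 were lower and 1279 higher (median -1.33), and within wild-type MeTPeak peaks 18850 and 899 (-1.28). On the RPM scale at the same bound on p, 13957 were lower (median -1.08), and without Lars2 and Rn45s 10428 (-0.97). Lists outside the central 95% numbered 3, 2 with means and 5 without matching on input level, where trophectoderm, fibroblast and m6A machinery lists were added and the zinc finger list was within it. Members of all lists with a peak in MEF numbered 133, and 81 with lists of equal length. The median of ribosomal protein genes turned to 0.007 on the RPM scale and 0.17 without Lars2 and Rn45s, and that of cell cycle genes to 0.086 without them. Among the other 172 alternatives, for single lists, pairs and input counts, 84 stayed the same, 80 moved without a change of sign, 2 lost and 3 gained a place outside the central 95%, and 3 were reversed, those just given.

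Leaving out each replicate, the replicate as a block, DESeq2 and other normalizations were not run, because the files hold no values per library, and the position of peaks in genes was not run for want of an mm9 or hg19 annotation. No paired analysis was possible because each genotype and library kind has 1 pooled column. FDR under 0.1 adds no region, since the table holds few beyond 0.05. Depth limits the values under 50 reads, 3155 regions of the table, and the fifth of regions with the fewest reads had a median of -2.93 against -0.96 in the fifth with the most.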

Other observations

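The list of imprinted genes was written after the input values of Plagl1 and Peg10 had been seen, so it tests nothing about such genes as a group. Whether each is expressed from the copy of 1 parent in these cells was not tested. Of its 58 genes, 7 had at least 500 input reads in the genotype table, each taken from 1 listed region. Plagl1 was at -4.04 (log2 ratio of input RPM in Mettl3 KO to wild-type, -4.35 to -3.72), Peg10 at -2.93 (-3.26 to -2.60), Zdbf2, which is expressed from the paternal copy, at -2.32 (-2.56 to -2.09) and Cd81 at -1.20 (-1.40 to -1.01). Gab1 was at -0.56, Gnas at 0.21 and Peg3 at 0.35, so members went both ways, and leaving out Lars2 and Rn45s raises each by 0.31. No explanation was tested, and with pooled libraries a difference between cultures is not excluded.

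Kcnq1ot1, an imprinted antisense noncoding RNA, had 83 MeTPeak peaks in Mettl3 KO, with a highest fold of 8.50, and none in wild-type. Neat1, which builds paraspeckles, went from 15 peaks in wild-type (highest fold 33.0) to 36 in Mettl3 KO (9), and Rian from 1 (42.7) to 5 (3.50). Ribosomal protein genes with a MeTPeak peak in Mettl3 KO and none in wild-type included Rpl21 at 4, Rps26 at 3.50 and Rpl15 at 3.33. Mettl14 had 3 peaks in Mettl3 KO (3.75) and none in wild-type. These genes were chosen after their values were seen.

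Across the 5 mouse lists, 237 peaks had the same start and end in each, and 796 of 45611 merged regions were in all 5, while 34357 were in 1 list. Regions lower in Mettl3 KO overlapped EPSC peaks 1.71 times (1.52 to 1.95) and MEF peaks 1.41 times (1.34 to 1.48) as often as higher regions of like input reads and length. These regions were not matched on wild-type m6A-CT reads either, so the limits given for the E14 overlap hold here too.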
